A study of Mus musculus with 3 samples.

How the data were processed

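2-cell embryos of 3 litters were collected at embryonic day 1.5 and lysed in a direct lysis buffer, per the labels' protocols. RNA was amplified with SPIA (Nugen Ovation kit), the cDNA was sheared with a Covaris instrument, and Illumina libraries were made, per the labels. Reads were aligned with Bowtie to mm9, per the submitters' processing notes. The Bowtie version and its settings for mismatches and multiple matches are not given in the sources used here. The deposited values are coverage (signal), the number of aligned reads over each base, written as a bedGraph track of a sorted alignment file, per the file headers. The authors' coverage is unscaled whole numbers, and values of 1000000 or more, which occur on the mitochondrial chromosome, are rounded to 6 digits.

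Alignments were recovered from coverage. On every nuclear chromosome the coverage split exactly into ungapped alignments of 72 bases, with 0 negative starts in every litter, so each alignment's start is known and its strand is not. On simulated data, 100% of 50000 positions were recovered. The values are called alignments because a read that fits several places can be counted at each. Totals were 48850485, 45409692 and 54920692 alignments in litters 1 to 3.

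The files use mm9, and an annotation of that build was not used here. As fixed before the data were examined for that case, 10 kb windows took the place of genes, and genes were named only on the mitochondrial chromosome. Its length in the files is 16299 bases. Gene positions there come from the GENCODE M21 annotation, made for GRCm38, in which the mitochondrial chromosome is the same reference sequence by general knowledge, not by comparison of sequences here. The frame was checked on the coverage: the difference between long genes and tRNA genes was 4.97 on the log2 scale at the annotated place, and 50 of 16299 circular shifts gave one as large, the best at a shift of 24 bases. The gene lists fixed before the data were examined were used only for the mitochondrial genes. The results that need nuclear genes or strand (gene lists, the oocyte against 2-cell list, exon and intron origin, and strand share) were not analysed here.

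Levels of mitochondrial genes are the mean coverage over bases that belong to no other gene, divided by the mean over the chromosome. Window densities are RPKM (alignments per kb of sequence per 1000000 nuclear alignments), with a pseudocount of 0.1 on the log2 scale, and a window counted as expressed at 1 or more in all 3 litters. A limit of 3 alignments, the upper limit that a count of 0 allows by counting error alone, equals 0.00882, 0.00925 and 0.00741 RPKM in litters 1 to 3. Scaling by the median of ratios over windows gave factors of 0.972, 1.17 and 0.880 relative to the nuclear total. The spread is the median coefficient of variation over windows with a mean of at least 100 alignments, less the counting variance. On 30801 simulated windows with a variation of 30% it returned 24.55%, so the median of 3-litter values runs low. Of windows changed by 8 fold in the simulation, 100% were found over 2 fold, as were 11.5% of unchanged ones.

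The windows named were fixed beforehand as the 10 with the most alignments, with neighbours in a run counted together, and the 5 with the largest SD of log2 density among those with a mean of at least 100 alignments. Nuclear bins of 200 bases with at least 500 alignments and 40 start positions in every litter were compared with every place on the mitochondrial chromosome, in both orientations, by the correlation of log start counts. The minimum correlation of 0.97 in all litters was chosen after seeing the data: at 0.9, 237 bins matched but 47 also matched a shuffled pattern. The planted copies in a simulation of 30 bins were found in 80% of cases.

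The 3 litters are separate collections per the labels, and values are means with SD over litters. The mitochondrial share has 95% Wilson intervals and a chi-square test of alignments over libraries, which compares the 3 libraries and not conditions. Ratios were tested with an exact two-sided sign-flip permutation test. Alternatives were the expression threshold, the window size, the pseudocount, filters on low windows, distinct start positions, the scaling and leaving out each litter. Respiratory complex groups, gene ratios, the X to autosome ratio, the profile search, the overlap of windows between litters, the values without windows of mitochondrial pattern or without the top window of chromosome 17 and the counts shared between places were chosen after seeing the data. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.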

Results

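RNA was profiled in mouse embryos at the 2-cell stage (embryonic day 1.5). Each library came from a litter of embryos. There was 1 group of 3 litters, numbered 1 to 3 in the labels. The mothers were homozygous for a floxed allele of LSD1, a histone demethylase gene, and lacked ZP3::Cre, a transgene that expresses Cre recombinase in growing oocytes. The fathers were wild type. The RNA had been amplified with SPIA, an isothermal method that copies RNA into cDNA along its length. The deposited values were read coverage per base, and 72-base alignments were recovered from them. They numbered 48850485 in litter 1, 45409692 in litter 2 and 54920692 in litter 3. Of these, 34014013, 32431630 and 40474940 lay on nuclear sequence. With 1 group, the design gives a description of the 2-cell transcriptome and of the spread between litters, and no contrast between conditions.

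Alignments on the mitochondrial chromosome made up 28.4% ± 2.04 of all alignments (SD, n = 3). All alignments were ungapped, and reads that fit several places were counted at more than 1, so this is no share of transcripts. The share was 30.4% in litter 1, 28.6% in litter 2 and 26.3% in litter 3. Within this chromosome the ribosomal RNA genes mt-Rnr1 and mt-Rnr2 took 60.1% ± 6.39 of the aligned bases, and the 13 protein genes took 39.3% ± 6.41. The 22 tRNA genes took 0.294% ± 0.0632, and the control region (bases 15423 to 16299), which holds the start sites of mitochondrial transcription, took 0.343% ± 0.0169. The tRNA genes are 59 to 75 bases long, and only mt-Tl1 is long enough to hold a whole 72-base alignment. Their coverage therefore does not measure the amount of mature tRNA. Alignments of longer molecules that span a tRNA gene still count over its bases. How far read length lowers the coverage was not tested. Litter 3 gave the ribosomal RNA genes the highest share, at 67.4%, against 55.6% in litter 1 and 57.2% in litter 2.

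The 95% Wilson intervals of the mitochondrial share were 30.36% to 30.38%, 28.57% to 28.59% and 26.29% to 26.31% for litters 1 to 3, so the litters differed by more than counting error. A chi-square test of the alignments, which compares the 3 libraries only, gave a statistic of 212792 on 2 degrees of freedom. The intervals cover counting error only, because amplified reads without molecular identifiers are not independent molecules. Leaving out nuclear bins that repeat the mitochondrial pattern gave a share of 27.4% to 32.4% across litters.

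**Figure D1:**
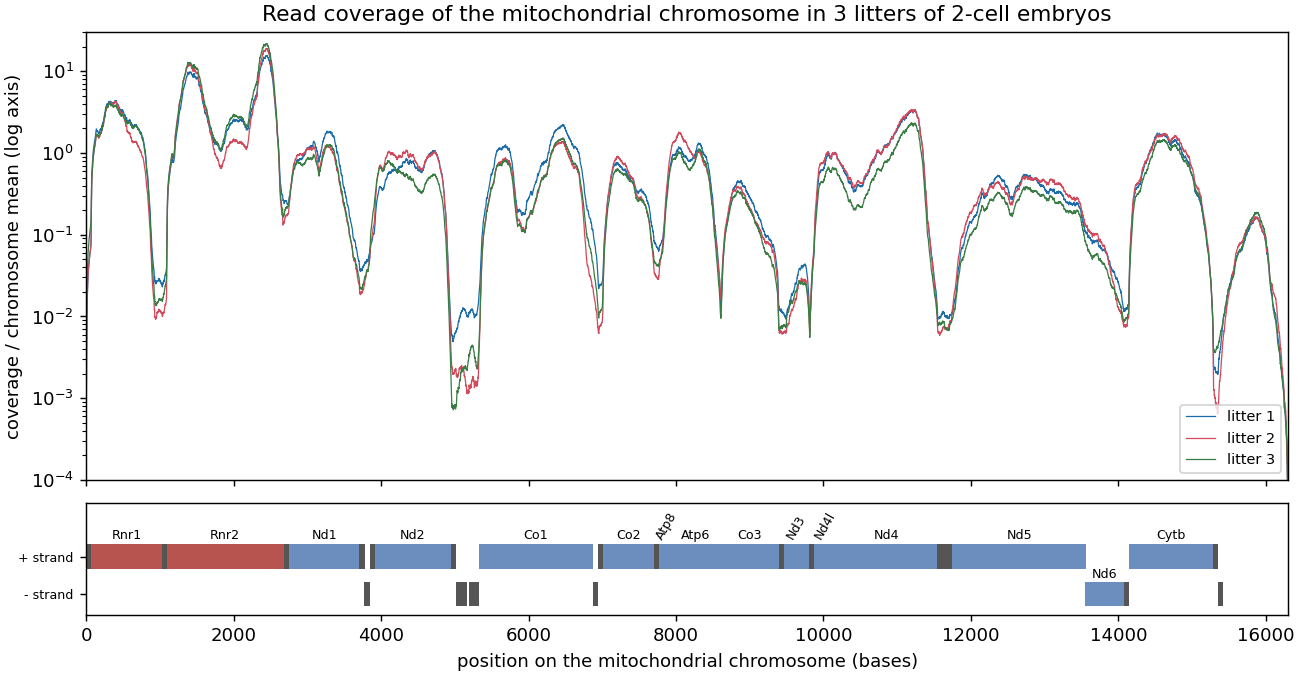
Coverage of each base of the mitochondrial chromosome divided by the chromosome mean (log axis) in litters 1 to 3, above a map of its genes on both strands (red, ribosomal RNA; blue, protein; grey, tRNA). The highest point lies at base 2454 in mt-Rnr2, and coverage falls between most genes.

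mt-Rnr2, the RNA of the large subunit of the mitochondrial ribosome (bases 1094 to 2675), was the most covered gene, at 5.04 ± 0.679 times the mean of the chromosome (SD, n = 3). mt-Rnr1, the RNA of the small subunit (bases 70 to 1024), reached 1.90 ± 0.157. Among protein genes mt-Nd4 led at 1.06 ± 0.241, followed by mt-Cytb at 0.787 ± 0.0894, mt-Atp6 at 0.780 ± 0.115, mt-Nd1 at 0.731 ± 0.123 and mt-Nd4l at 0.649 ± 0.150. mt-Nd3 was lowest at 0.0204 ± 0.00471, below mt-Nd6, the only protein gene annotated on the minus strand, at 0.0530 ± 0.0127.

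Grouped by respiratory complex, the 7 subunits of complex I, the NADH dehydrogenase, held 21.7% ± 4.27 of mitochondrial aligned bases. The 3 subunits of complex IV, cytochrome c oxidase, held 8.55% ± 1.79. mt-Cytb, the mitochondrially encoded subunit of complex III, held 5.53% ± 0.628, and the ATP synthase genes mt-Atp6 and mt-Atp8 held 3.56% ± 0.552. These shares are not corrected for length, and the groups span 6340, 3013, 1144 and 842 bases in this order. By median gene coverage, complex III was highest at 0.787 ± 0.0894 times the chromosome mean. Complex I had 0.594 ± 0.114, ATP synthase 0.518 ± 0.0797 and complex IV 0.406 ± 0.0471. Within complex IV, mt-Co1 stood at 0.631 ± 0.169 times the chromosome mean, mt-Co2 at 0.406 ± 0.0471 and mt-Co3 at 0.182 ± 0.0276. Within complex I, mt-Nd2 stood at 0.613 ± 0.140 and mt-Nd5 at 0.283 ± 0.0575. mt-Atp8 stood at 0.256 ± 0.0451, and at 0.406 with the bases it shares with mt-Atp6.

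Ratios between genes differed in how far the litters varied. Coverage of mt-Atp6 exceeded that of mt-Atp8, with which it overlaps, by 3.06 ± 0.130 fold over bases of a single gene, and by 1.96 ± 0.136 fold with the shared bases counted for both. mt-Nd4 exceeded mt-Nd4l, which it also overlaps, by 1.64 ± 0.0597 fold. mt-Nd5 exceeded mt-Nd6 on the other strand by 5.38 ± 0.237 fold, and mt-Rnr2 exceeded mt-Rnr1 by 2.67 ± 0.449 fold. mt-Atp6 exceeded its neighbour mt-Co3 by 4.32 ± 0.609 fold. mt-Co1 exceeded mt-Co2 by 1.55 ± 0.375 fold, with 1.94 in litter 1, 1.19 in litter 2 and 1.54 in litter 3. mt-Nd4 exceeded mt-Nd3 by 53.3 ± 15.1 fold, mt-Co1 exceeded mt-Co3 by 3.44 ± 0.502 fold, and mt-Nd4 exceeded mt-Cytb by 1.34 ± 0.176 fold. The median ribosomal RNA gene exceeded the median protein gene by 6.59 ± 1.41 fold, and the median protein gene exceeded the median tRNA gene by 56.0 ± 7.71 fold. The ratio to tRNA genes is no measure of tRNA abundance, because nearly all of them are shorter than a 72-base alignment. Each of these 11 ratios was above 1 in 3 of 3 litters. A two-sided exact sign-flip permutation test gave p = 0.25 for each, the smallest p that 3 litters allow. The ratios were chosen after the levels had been seen, and reads carry no strand, so mt-Nd6 cannot be separated from transcripts of the opposite strand.

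**Figure D2:**
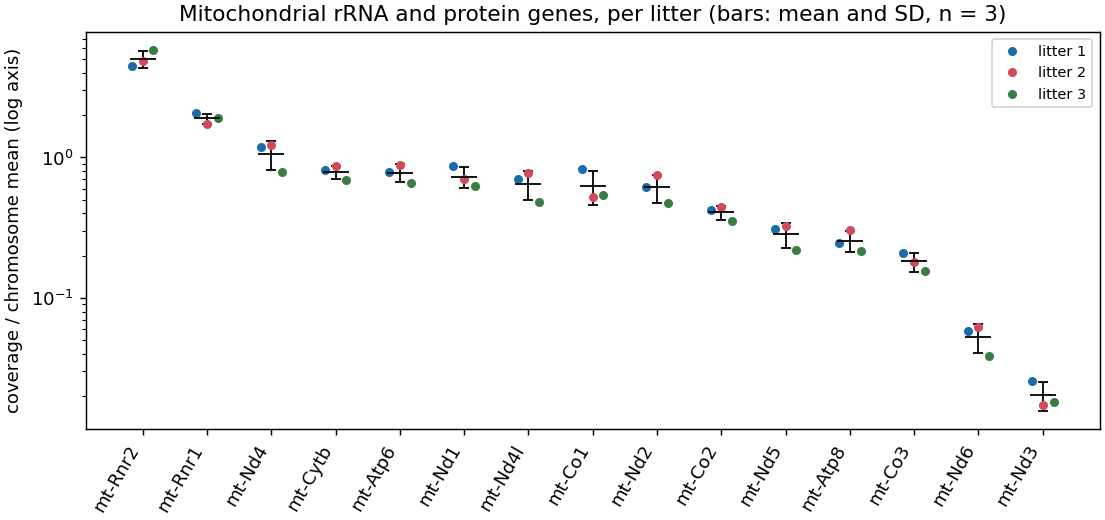
Coverage of the 2 ribosomal RNA and 13 protein genes divided by the chromosome mean (log axis), with a point per litter and the mean and SD over 3 litters. Genes run from mt-Rnr2 at 5.04 to mt-Nd3 at 0.0204.

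The order of the 15 genes was alike between litters. Across genes, Pearson correlations of log2 coverage were 0.989 for litters 1 and 2, 0.994 for litters 1 and 3 and 0.987 for litters 2 and 3. Spearman correlations were 0.911, 0.971 and 0.968. Genes are not independent replicates, and no p-value is given.

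Nuclear alignments were concentrated in a small part of the genome. Of 272592 windows of 10 kb, 8639 (3.17%) reached 1 RPKM (alignments per kb of sequence per 1000000 nuclear alignments) in all 3 litters, and these held 77.3% of nuclear alignments. The number reaching this level was 13706 in litter 1, 15093 in litter 2 and 14240 in litter 3. In 32.7% of windows no litter had any alignment. Covered bases amounted to 2.34%, 3.12% and 2.19% of the nuclear genome in litters 1 to 3. The 1000 windows with the most alignments held 43.4% of the nuclear total, and the top 100 held 22.2%. Without the 5 windows that contain bins of mitochondrial pattern, described with the named windows, these shares were 37.0% and 13.5%. The threshold corresponded to 340, 324 and 405 alignments per window in litters 1 to 3. The number changed by over 1.5 times with another threshold or window size, and when repeated positions were left out.

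Chromosome 11 had the highest density among the assembled chromosomes after bins with the mitochondrial pattern were left out, at 0.557 ± 0.0164 RPKM (SD, n = 3). It was also highest by distinct start positions. Its density includes a run of windows from 60.40 to 60.51 Mb at 88.6 ± 10.5 RPKM. In that run, 93.8% of 2337 start positions with at least 50 alignments in every litter had litter counts found elsewhere. The density of chromosome 11 without this run was not calculated. Chromosome 17 had 0.513 ± 0.0813 and chromosome 13 had 0.458 ± 0.0187. The value of chromosome 17 rests on the window from 39.98 to 39.99 Mb, without which it was 0.371 ± 0.00712, and by distinct start positions it ranked 8 of 19 autosomes. The lowest autosomes were chromosome 14 at 0.252 ± 0.00898 and chromosome 3 at 0.260 ± 0.00441. The share of windows at or above 1 RPKM in all litters was 4.68% on chromosome 11 and 2.54% on chromosome 14. With all nuclear alignments counted, chromosome 1 was highest at 0.613 ± 0.0582. Its value without those bins was 0.412 ± 0.00794. Litters differed most on chromosome 17, where the same window was lower in litter 2.

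Without bins of mitochondrial pattern, the X chromosome had 0.280 ± 0.0402 RPKM and the Y chromosome had 0.0303 ± 0.00318. With all nuclear alignments counted, X had 0.259 ± 0.0386 and Y had 0.0280 ± 0.00244. The values that follow use all nuclear alignments. The density of X was 0.740 ± 0.112 of the median autosome (SD, n = 3), with 0.655 in litter 1, 0.866 in litter 2 and 0.698 in litter 3. X lay below 19 of 19 autosomes in litter 1, 13 in litter 2 and 17 in litter 3. A two-sided exact sign-flip permutation test of the log2 ratio gave p = 0.25, the smallest that 3 litters allow. The sex of the embryos is not given in the labels.

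**Figure D3:**
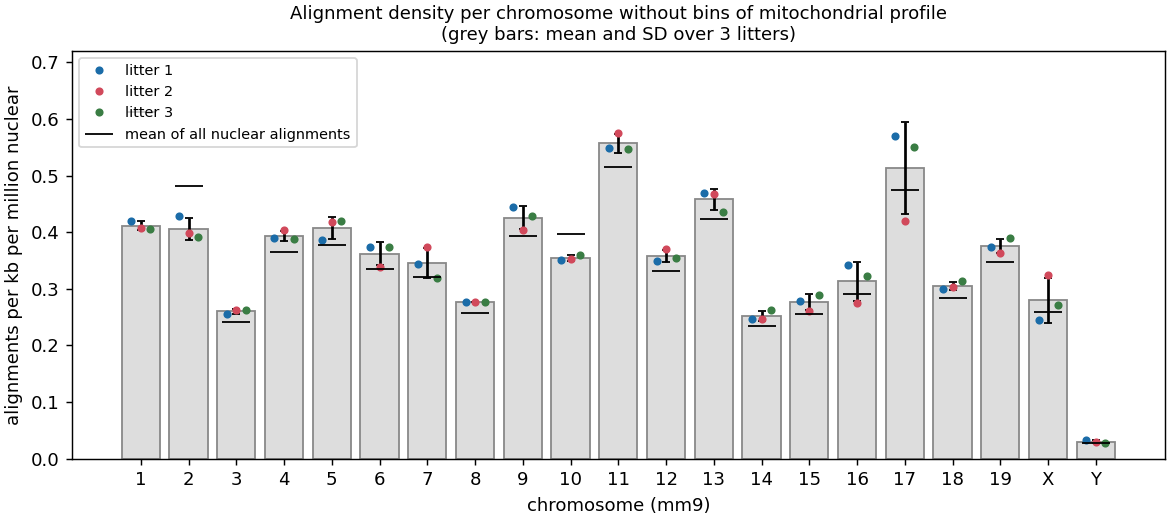
Density in alignments per kb per 1000000 nuclear alignments (RPKM) on each assembled chromosome. Grey bars with SD are means over 3 litters without bins of mitochondrial pattern, points are litters, and black lines are means of all nuclear alignments. Chromosome 11 is highest at 0.557 and Y lowest at 0.0303.

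The windows with the most alignments lay on chromosomes 1, 2, 10 and 17. On chromosome 1, the window from 24.62 to 24.63 Mb held 33573 ± 7716 alignments per 1000000 nuclear alignments (SD, n = 3). On chromosome 2, the window from 22.44 to 22.45 Mb held 31328 ± 9816. On chromosome 10, the window from 95.54 to 95.55 Mb held 15934 ± 930.3. These 3 windows contain bins whose read starts repeat the pattern of the mitochondrial chromosome. The window from 39.98 to 39.99 Mb on chromosome 17 contains none and held 12525 ± 6836, with 17446 in litter 1, 4720 in litter 2 and 15409 in litter 3. The next 6 lay at 11.14 Mb on chromosome 16 (4169 ± 1765), 85.26 Mb on chromosome 13 (4165 ± 1100), 56.83 Mb on chromosome 1 (3568 ± 2119), 56.07 Mb on chromosome 9 (3498 ± 1351), 51.24 Mb on chromosome 13 (2848 ± 1103) and 8.23 Mb on chromosome 11 (2224 ± 1005).

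Positions are on mm9, and no nuclear gene is named because an annotation of that build was not used here. The value of each of these windows fell by over 1.5 times when every start position was counted a single time. A 10 kb window has few positions to fill at this depth, so a fall follows in part from depth. The chromosome 1 window from 24.62 to 24.63 Mb had 2989 to 2993 start positions per litter. The fall is therefore no measure of duplication.

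The chromosome 1 copy of mitochondrial sequence ran from 24618401 to 24623021, in reverse orientation, and matched mitochondrial bases 6396 to 11015. This stretch covers part of mt-Co1 and mt-Nd4 and the genes between them. The number of alignments starting at each position was equal on both chromosomes at 98.4%, 98.5% and 98.4% of 4550 positions in litters 1 to 3. The nuclear total was 100.1% of the mitochondrial total over this stretch in each litter. In all, 31 of 5567 tested bins of 200 bases repeated a mitochondrial pattern, on chromosomes 1, 2, 4 and 10, and held 7.40% ± 1.75 of nuclear alignments. None of the tested bins matched a shuffled mitochondrial pattern at the same limit of 0.97. That limit was raised from 0.9, where 47 bins had matched the shuffled pattern, so this is no independent support.

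**Figure D4:**
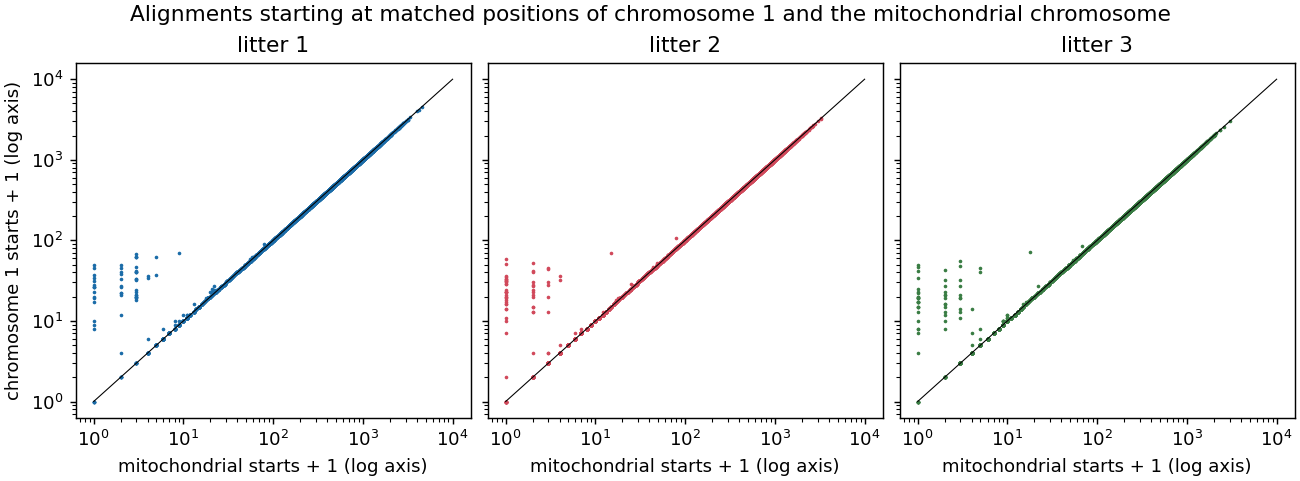
Alignments starting at each of 4550 matched positions on the mitochondrial chromosome (x axis) and on chromosome 1 (y axis), plus 1, on log axes, for litters 1 to 3. Counts lie on the line of equality at 98.4% to 98.5% of positions.

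Litters shared the windows at or above 1 RPKM in part and differed widely in the amount at low levels. Of 21743 windows at that level in any litter, 39.7% were at that level in all 3, 4018 in 2 litters and 9086 in 1. Each pair of litters shared 52.4% to 53.8% of the windows at that level in either. Pearson correlations of log2 density over all windows were 0.852 for litters 1 and 2, 0.851 for litters 1 and 3 and 0.837 for litters 2 and 3. Spearman correlations were 0.703, 0.691 and 0.687. Among 30801 windows with a mean of at least 100 alignments, the median coefficient of variation between litters was 60.4% after counting variance was removed. This removes counting error only, so noise of the amplification remains in the value, which was 47.9% with distinct start positions. It was 98.8% in windows with 10 to 100 alignments, 70.7% with 100 to 1000, 30.4% with 1000 to 10000 and 18.9% with 10000 or more. The window at 51.24 Mb on chromosome 13, with 3189 to 3352 start positions per litter, and the window at 8.23 Mb on chromosome 11, with 1344 to 1372, were each higher in litter 2 than in both other litters.

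Between litters 1 and 2, 15458 windows (50.3%) differed by over 2 fold, with 9169 higher in litter 2. Between litters 1 and 3, 16258 (52.9%) differed, with 8328 higher in litter 3. Between litters 2 and 3, 16824 (54.7%) differed, with 7423 higher in litter 3. Each litter is a single library, so no window was tested. The chi-square statistic per degree of freedom was 233, 242 and 284 for the 3 pairs, so no pair was a library deposited again.

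The 5 windows with the largest SD of log2 density were each covered mainly in 1 litter. The window at 34.44 Mb on chromosome 9 held 5510 alignments in litter 1, 2 in litter 2 and 8 in litter 3. The window at 41.80 Mb on chromosome 15 held 4337 in litter 3, against 1 in litter 1 and 3 in litter 2. The window at 169.84 Mb on chromosome 2 held 3223 in litter 2, against 0 in litter 1 and 4 in litter 3. Windows at 118.54 Mb on chromosome 14 and 7.99 Mb on chromosome 9 held 12038 and 7617 alignments in litter 3, and at most 331 and 68 in the other litters.

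Repeated alignments, those that start where an earlier alignment of the same litter starts, made up 78.8% ± 3.34 of all alignments (SD, n = 3) and 70.4% ± 4.80 of nuclear ones. The share was 80.6%, 74.9% and 80.8% in litters 1 to 3. At 10000000 random alignments per litter it was 62.6% ± 3.17. Reads that fit several places were counted at more than 1 of them. Of 22256 nuclear start positions with at least 50 alignments in every litter, 55.2% had a set of 3 litter counts that recurred elsewhere, at up to 19 places, against 0.997% after the counts of litter 2 were shuffled among nuclear positions and 10.9% when they were shuffled only among positions of similar depth.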

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

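Alignments on the sequences that mm9 labels as random, called contigs here, enter no comparison of chromosomes. They do enter the nuclear totals and the window counts. In every litter, 11 contigs exceeded the 3 alignments that a count of 0 allows by counting error alone. Contig 1_random had 10.3 ± 2.03 RPKM, alignments per kb per 1000000 nuclear alignments (SD, n = 3), which is 29.3 times the median autosome. Contig 5_random had 8.49 ± 1.42 and contig 8_random had 5.73 ± 1.06. On 1_random, 48 of 124 windows were at 1 or more in all litters. Contigs 4_random, Un_random and 13_random had 2.76 ± 0.211, 1.32 ± 0.169 and 1.22 ± 0.326. Contigs 17_random, 7_random and 9_random had 0.287 ± 0.0371, 0.257 ± 0.0629 and 0.141 ± 0.0368, and X_random and Y_random had 0.0500 ± 0.0226 and 0.0201 ± 0.00321. Among start positions with at least 50 alignments in every litter, those with litter counts found elsewhere were 92.7% of 41 in Un_random, 100% of 12 in 5_random, 60% of 5 in 1_random and 0% of 17 in Y_random.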

How the results depend on the processing

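For the results that answer a comparison, 31 alternative values moved (values by over 1 SD, counts by over 1.5 times) and 35 stayed within that. Reversal of direction was not assessed, since with 1 group most of these results have no direction. Counting distinct start positions gave a mitochondrial share of 0.154%, because the chromosome has few positions to fill, 13789 expressed windows, a mean Pearson correlation of 0.825 and a spread of 47.9%. The mitochondrial share stayed within 1 SD, at 27.4% to 32.4% across litters, with the profile bins left out, and was 33.7% with them counted in, which counts reads placed on both chromosomes again. Both were added after seeing the data. The repeated share was 70.4% on nuclear sequence and 62.6% at 10000000 random alignments. Expressed windows numbered 25533 at a threshold of 0.1 and 2343 at 5. Windows of 1 kb gave 32461 expressed windows, 12.1% with any alignment, a correlation of 0.697 and a spread of 67.2%. Windows of 100 kb gave 1685, 94.5%, 0.943 and 38.6%, and 4176, 4423 and 4839 windows over 2 fold for pairs 1 and 2, 1 and 3, and 2 and 3. These counts follow from the number of windows and the thresholds. The correlation was 0.879 with a pseudocount of 1, 0.740 at a mean of 10 or more alignments and 0.620 at 100 or more, the last added after seeing the data. The spread was 82.4% at a mean of 10 or more and 29.9% at 1000 or more, where 1317, 1337 and 1541 windows differed over 2 fold. Leaving out each litter gave a spread of 46.5% to 52.9%, below the 60.4% of all 3 litters whichever was left out. A median from pairs of litters is not like for like with one from 3 litters, so the fall is not evidence about any 1 litter. The cause of these shifts was not tested. Among single genes, windows and shares, 17 values moved by over 1 SD and 159 did not, and 10 of the 17 were the windows with the most alignments under distinct positions. The 159 include the 5 windows of largest SD, whose SD exceeds their mean and which rest mainly on 1 litter. Per 1000000 nuclear alignments, the windows at 34.44 Mb on chromosome 9, 169.84 Mb on chromosome 2, 41.80 Mb on chromosome 15, 118.54 Mb on chromosome 14 and 7.99 Mb on chromosome 9 had 54.1, 33.2, 35.8, 102.7 and 63.7, and 0.130 without litter 1, 0.0494 without litter 2, and 0.0610, 5.36 and 1.45 without litter 3. With distinct positions they had 11.3, 13.5, 15.6, 41.8 and 21.1. With shared bases counted, mt-Atp8 was 0.406 and the ratio of mt-Atp6 to it 1.96. Chromosome 17 was 0.401 with distinct positions and 0.371 without its top window. The share of nuclear alignments in profile bins was 11.4% at a minimum correlation of 0.9, and the top 100 and top 1000 windows held 13.5% and 37.0% without windows of mitochondrial pattern. Leaving out the top window, the lower minimum correlation and leaving out windows of mitochondrial pattern were added after seeing the data. Whole gene span, shared exon reads, length-matched lists, 5′-end repeats, strand and exon assignment were not run, since they need nuclear genes or strand. No paired analysis was possible because there was 1 group. At this depth a count of 0 in a window allows up to 0.00741 to 0.00925 RPKM.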

Other observations

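The runs of neighbouring windows at 1 RPKM or more in all litters numbered 6560, of which 5240 were 1 window long and 4 were 10 windows or longer. These were described after the values were seen. On chromosome 11 a run of 11 windows from 60.40 to 60.51 Mb had 88.6 ± 10.5 RPKM (SD, n = 3), and 93.8% of its 2337 deep start positions had litter counts found elsewhere. On chromosome 6 a run of 10 windows from 119.87 to 119.97 Mb had 12.5 ± 2.23, with 6.67% of 15 deep positions shared. On the X chromosome a run of 8 windows from 12.72 to 12.80 Mb had 37.6 ± 12.9. Runs from 10.06 to 10.14 Mb on chromosome 18 and from 121.25 to 121.33 Mb on chromosome 2 had 8.10 ± 1.72 and 5.74 ± 1.20. The longest, 16 windows, lay on contig 1_random.

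Coverage within mitochondrial genes leaned to different ends. From the midpoint on, the 3′ part of mt-Nd4 held 72.1% ± 1.26 of its coverage, mt-Co1 66.5% ± 1.70 and mt-Nd6 72.5% ± 4.06, while mt-Rnr1 held 26.2% ± 4.36, mt-Co3 29.5% ± 1.76 and mt-Cytb 40.5% ± 1.76. The 3′ end of mt-Nd6 overlaps the more covered mt-Nd5 on the other strand, and mt-Nd6 coverage peaked at base 13552 in that overlap. Without strand, the lean of mt-Nd6 cannot be separated from reads of mt-Nd5. The tRNA genes were lowest as a group, with a median of 0.00973 ± 0.00219 times the chromosome mean, and mt-Tl1, next to mt-Rnr2, was highest among them at 0.210. mt-Tl1 is also the only tRNA gene long enough, at 75 bases, to hold a whole 72-base alignment.

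The patterns below were noticed in the data. The tests of counting at another place, of mitochondrial DNA, of single molecules and of shared reads were set only after the values they measure had been seen. No biological explanation was tested, since there is 1 group.

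Nearly the same start counts appeared on the mitochondrial chromosome and on its copy on chromosome 1, equal at 98.4% or more of positions in each litter. This is consistent with reads of mitochondrial transcripts that fit both places being counted at both. Transcripts running through the nuclear copy are argued against, because density within 2 kb on either side was at most 6.29e-05% of that inside. Mitochondrial DNA as the source of most mitochondrial reads is argued against, because median tRNA gene coverage was at most 2.00% of that of the protein genes in any litter. Transcripts that begin and end within the nuclear copy were not tested.

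In 743, 1417 and 731 windows of litters 1 to 3, at least 100 alignments lay in that litter and at most 3 in each other litter. A candidate explanation is the amplification of single molecules. At least 77.3% of these windows in every litter had 80% or more of their alignments starting within 1 kb, against at most 46.8% of windows of matched alignment number shared by all litters. Fragments of genomic DNA stay open. Over 19 autosomes, these windows per megabase correlated with expressed windows at Spearman rho = 0.489 (permutation p = 0.0348) and Pearson r = 0.538 (permutation p = 0.0179). Pearson r was 0.313 without the 2 chromosomes farthest from the median. Their coefficient of variation over autosomes was 10.4%, against 8.41% from counting alone. So little variation beyond counting means that the correlations cannot decide. Short exons transcribed in 1 litter only stay open too.

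Of 268 windows with a mean of at least 300 alignments per 1000000 nuclear alignments, 27 on 16 chromosomes lay in litter 2 more than 3 fold below both other litters, and 0 had such a low value in litter 1 or in litter 3. The ratio of litter 2 to the mean of the others lay between 0.180 and 0.318, and the chromosome 17 window at 39.98 Mb is among them. These windows held 5.60%, 1.27% and 4.72% of nuclear alignments in litters 1 to 3. The scaling of litter 2 is argued against, because the median ratio over all expressed windows was 0.947. The same reads counted at several windows may contribute, but the measure used cannot decide this. In these windows 42.9% of 2357 deep start positions had litter counts found elsewhere, against 57.7% in the other windows at this level. A low share does not exclude shared reads. Among the top windows with bins of mitochondrial pattern, the share was 99.7% on chromosome 1 but 22.3% on chromosome 2 and 15.2% on chromosome 10.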
